A study of Homo sapiens with 28 samples.

How the data were processed

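The series measured protein and histone mark binding by CUT&RUN, in which a protein A and micrococcal nuclease fusion cuts DNA next to an antibody, in IMR-90 ER:Ras cells. These are human fetal lung fibroblasts that carry an oncogenic Ras switched on by 4-hydroxytamoxifen, which drives them into senescence. Per the labels' protocols, cells received 100 nM 4-hydroxytamoxifen for 6 days, small interfering RNAs by transfection, and a spike-in of yeast DNA. Whether the spike-in entered the processing is not given in the sources used here. There were 3 antibodies, with 14 libraries for H3K27ac, an acetylation mark of active enhancers and promoters, 8 libraries for FOXF1, a forkhead transcription factor of lung mesenchyme, and 6 for phosphorylated c-JUN (p-c-JUN), a subunit of the AP-1 transcription factor.

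The 28 deposited files were peak lists in narrowPeak format, one per library with none pooled, 22 from a first deposit and 6 from a second, told apart by their record numbers. Bowtie2 2.3.4.1, SAMtools 1.9, deepTools 3.1.1 and MACS2 3.0.0 with build hg19 were named per the submitters' processing notes, without parameters. Each deposited peak had a display score, a fold enrichment over the local background at its summit, and −log10 values of its p and q, all as the authors' peak caller wrote them. These values were used only to describe, rank or filter peaks within a list. No control library was named in the sources used here, and the number of mapped reads is unknown. The FOXF1 lists after siFOXF1/2 carried another peak name prefix than the rest of the first deposit, and their narrowest peak was 76 bp long against 182 to 245 bp elsewhere.

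Depth was therefore estimated from the lists. Summit pileup and background were solved from fold and −log10 p as the deposited files gave them, which returned a whole pileup within 0.0005 for 100% of peaks with −log10 p under 60 in every list. The 0.1% quantile of the background, divided by the narrowest peak, gave fragments per kilobase. This ranged from 2.21 to 8.28, with 1 value per library and no count behind it to give an interval. In the shortest lists the quantile rests on very few peaks and may lie above the true floor of the background. Peak numbers were not corrected for depth.

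Groups came from sample titles, 13 in all, with 2 libraries each except H3K27ac in senescent cells (2 in each deposit). The labels conflict in places. Proliferating (Pro) samples carried the same treatment and senescent cell type tags as the senescent (Sen) samples. The JUN knockdown was titled for cJUN and JUND, while its treatment tag also named JUNB. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No lists were identical. Replicate numbers were shared between groups without a stated pairing.

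Peaks on chromosomes 1 to 22 and X were kept, which left out 475 of 1123812 (0.0423%). For each of 9 comparisons, the peaks of the 4 libraries were joined into regions by an overlap of at least 1 bp. A region was gained when both libraries of the second condition and neither of the first held a peak, and lost when the reverse held. Regions held by exactly 1 library of each condition (4 pairs per comparison) showed how many such regions arise between unlike libraries. Log2 peak numbers were compared by an exact two-sided permutation test, which with 6 arrangements cannot give a p below 0.333. The regions named are, per comparison, the 10 gained and 10 lost with the best worst rank by −log10 q over the 2 libraries that held them. Coordinates are hg19, counted from 1.

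Overlap of FOXF1 regions (a peak in both libraries) with other lists was set against 200 random shifts along each chromosome, with 95% intervals from 1000 draws of chromosomes. Such intervals cover variation along the genome, not between cultures. Loss of regions by FOXF1 or p-c-JUN overlap was given as a Mantel-Haenszel odds ratio within 10 strata of peak strength. These tests and their alternatives were chosen before the data were examined: −log10 q of 5 or more, an overlap of 50% of the shorter peak, lists cut to equal length, each replicate left out of peak and region counts, a replicate block, all 4 H3K27ac Sen libraries, no strata, and summits within 200 bp. Strata of strength and 5 widths, each replicate left out of overlap shares and odds ratios, overlaps among gained and lost sets (13 sets against each class of each comparison, of which a few are printed), overlaps of regions held by library pairs, distance to peak-free stretches, the odds between single Sen lists in strata of width, odds by overlap with regions that gained H3K27ac in senescence, and H3K27ac in senescence with the Sen libraries of the second deposit were added after the data had been seen.

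On simulated lists, planted gained and lost regions were recovered at 100% with 0 false calls in all 9 comparisons. Planting was without noise, so this tested the code and not the error rate. For p-c-JUN after siFOXF1/2, a planted odds ratio of 2 came back as 1.95 (95% interval 1.84 to 2.06) with strata over 59367 regions and as 1.08 without. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No genome or annotation of hg19 was used here, so regions are given by position, and the planned gene list and motif tests were not analysed here.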

Results

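CUT&RUN peak lists were collected for FOXF1, p-c-JUN and H3K27ac in proliferating and senescent IMR-90 ER:Ras fibroblasts, and in senescent cells after siRNA knockdown of FOXF1 and FOXF2 (siFOXF1/2), of the acetyltransferases p300 and CBP (sip300/CBP), or of JUN family members. The lists held from 133 to 93443 peaks. FOXF1 lists had 7251 ± 5388 peaks (SD, n = 2) in Pro cells, 27070 ± 19045 (n = 2) in Sen cells, 159.5 ± 37.5 (n = 2) after siFOXF1/2 and 630.5 ± 357 (n = 2) after JUN knockdown. The p-c-JUN lists had 28472 ± 5182 (n = 2) in Pro cells, 81810 ± 16452 (n = 2) in Sen cells and 80558 ± 7852 (n = 2) after siFOXF1/2.

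The H3K27ac lists had 86817 ± 3553 peaks (SD, n = 2) in Pro cells, 84864 and 60862 in the Sen libraries of the first deposit, 48859 and 26694 in those of the second, 78210 ± 9141 (n = 2) after siFOXF1/2 and 52045 ± 31734 (n = 2) after JUN knockdown. The sip300/CBP experiment had its own Sen control, whose lists were far shorter, with 5140 ± 4376 peaks (n = 2) against 2868 ± 1865 (n = 2) after the knockdown. Its estimated depth of 6.25 ± 0.783 fragments per kb was nevertheless close to the 6.59 and 8.10 of the first-deposit Sen libraries.

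**Figure D1:**
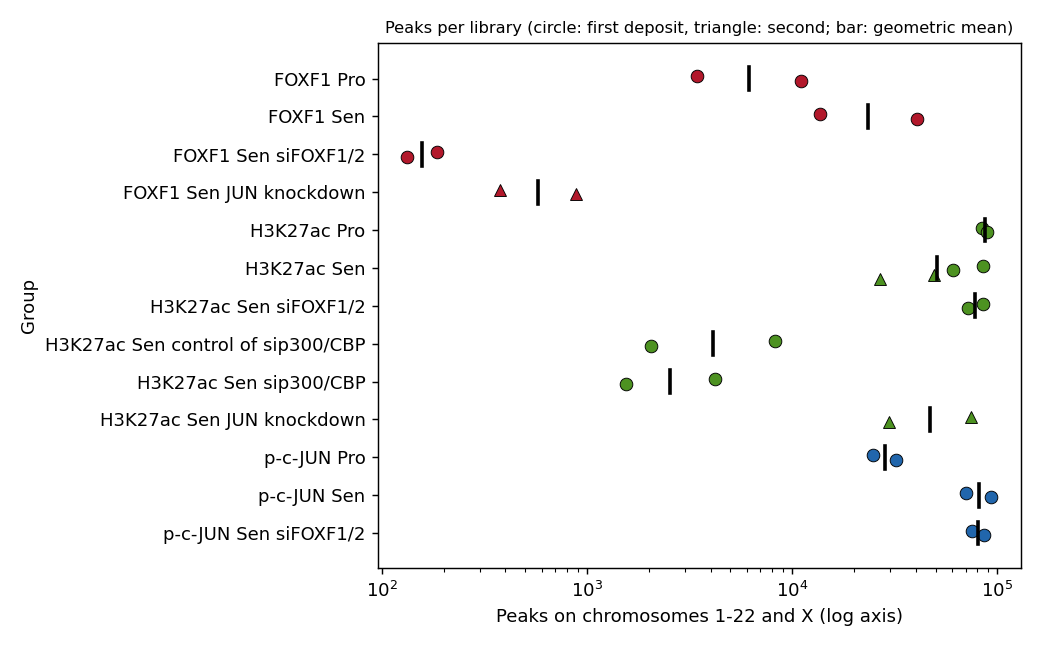
Peaks per library on a log axis, by group; circles are first-deposit and triangles second-deposit libraries, and bars mark geometric means over all libraries of a group. The FOXF1 lists after siFOXF1/2 (186 and 133 peaks) and after JUN knockdown (378 and 883) lie below all 4 FOXF1 lists of unperturbed cells (3441 to 40537).

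The first question was where FOXF1 was bound in proliferating and in senescent cells. FOXF1 was found at 5948 regions in both Sen libraries that neither Pro library held, and was lost at 159, a ratio of 37.4. The binding of proliferating cells was mostly kept: 76.5% and 92.9% of the 2722 regions shared by the Pro libraries held a peak in Sen replicates 1 and 2. The leading gained regions lay on chromosome 5 at 147751937 to 147752375 (fold enrichment 16.7 and 19.0 in the 2 Sen lists), chromosome 3 at 59489666 to 59490423 (16.2 and 18.8) and chromosome 8 at 19961034 to 19961672 (15.2 and 14.9). The leading lost region was on chromosome 4 at 31090389 to 31090818 (8.90 and 9.44). Of the gained FOXF1 regions, 66.8% overlapped a p-c-JUN region of Sen cells and 28.0% a p-c-JUN region itself gained in senescence, against 86.6% and 7.67% of FOXF1 regions held by all 4 libraries.

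Peak number rose by 1.93 ± 1.15 on the log2 scale (SE, n = 2 and 2; exact two-sided permutation p = 0.333, the smallest this design can give). Other library pairs shared 20 to 2665 regions. The estimated depth ratio, Sen over Pro, was 0.864. With all 4 lists limited to their 3441 best peaks, gained and lost came to 864 and 635, against 90 to 161 for other pairs, and without Sen replicate 1, the shorter list, gained and lost numbered 31811 and 194. Without Pro replicate 1 they numbered 6138 and 2470.

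In senescent cells given siFOXF1/2, few FOXF1 peaks were called. Of the 11287 regions held by both Sen libraries, 0.576% and 0.523% had a peak in the knockdown libraries, and 11215 regions were lost against 26 gained. The leading lost regions were on chromosome 9 at 94298534 to 94299046 (fold enrichment 25.5 and 31.2), chromosome 13 at 98953591 to 98954205 (21.0 and 22.5) and chromosome 2 at 14683053 to 14683673 (22.3 and 22.8). Of the 10 named gained regions, 3 lay within 2 Mb of the longest stretch of their chromosome that held no peak in any of the 28 lists.

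Peak number fell by 7.22 ± 0.824 on the log2 scale (SE, n = 2 and 2; exact two-sided permutation p = 0.333, the smallest possible). These 2 lists carried another peak name prefix, and their lowest −log10 q lay up to 0.916 above that of the Sen lists. Other library pairs shared 2 to 6 regions, lists of 133 peaks gave 56 gained and 67 lost (other pairs 0 to 1), and without Sen replicate 1 the lost regions numbered 40449.

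FOXF1 lists of JUN knockdown cells were short too, though longer than those after siFOXF1/2. The JUN knockdown libraries held 1.39% and 2.06% of the 11290 regions shared by the Sen libraries, and 10984 regions were lost against 64 gained. Of the lost regions, 73.7% overlapped a p-c-JUN region of Sen cells, as did 73.8% of those lost after siFOXF1/2, values set by the same Sen lists. The leading lost region was again that on chromosome 9 at 94298534. The gained regions were led by chromosome 10 at 42360110 to 42360911 (fold enrichment 6.40 and 5.11), and 6 of the 10 named lay within 2 Mb of the longest peak-free stretch of their chromosome.

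Peak number fell by 5.35 ± 0.997 on the log2 scale (SE, n = 2 and 2; exact two-sided permutation p = 0.333, the smallest possible). The knockdown libraries were of the second deposit and the Sen libraries of the first, so knockdown and deposit cannot be told apart. Other library pairs shared 3 to 179 regions, lists of 378 peaks gave 131 gained and 206 lost (other pairs 0 to 2), and without Sen replicate 1 the lost regions numbered 39999.

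Phosphorylated c-JUN was found at many more regions in senescence. Both Sen libraries held 29856 regions that neither Pro library held, against 327 lost, and the Sen libraries kept 95.9% and 96.9% of the 20376 regions shared in Pro cells. Gained regions were led by chromosome 3 at 43995382 to 43995928 (fold enrichment 25.0 and 28.8), chromosome 16 at 68435742 to 68436520 (23.6 and 23.2) and chromosome 5 at 81661557 to 81662200 (23.7 and 25.0). The leading lost region was on chromosome 5 at 31365169 to 31365692 (13.0 and 12.2). FOXF1 regions of Sen cells overlapped 7.63% of the gained p-c-JUN regions and 24.5% of those held by all 4 libraries.

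Peak number rose by 1.52 ± 0.278 on the log2 scale, a larger change than the spread within either group (SE, n = 2 and 2; exact two-sided permutation p = 0.333, the smallest possible). Depth was alike (Sen over Pro, 0.974), and other library pairs shared 200 to 1517 regions. With lists of 24808 peaks, gained and lost regions numbered 4244 and 3510, against 558 to 583 for other pairs. Without Sen replicate 1, gained regions numbered 61299.

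After siFOXF1/2, p-c-JUN gained about as many regions as it lost, 5730 and 5163, against 988 to 5530 for other pairs, and the knockdown libraries kept 81.5% and 87.3% of the 59347 shared Sen regions. The 2 classes differed in their overlap with FOXF1 regions of Sen cells: 11.6% of lost regions (95% interval 10.6 to 12.5) and 0.593% of gained regions (0.429 to 0.761) overlapped one, as did 2.02% to 4.61% of regions held by 1 Sen and 1 knockdown library. Regions held by all 4 libraries overlapped FOXF1 more often still, at 15.0%. Gained regions are absent from both Sen p-c-JUN lists, which overlapped 76.3% and 84.7% of the FOXF1 regions. The contrast between lost and gained regions is thus partly set by construction. The leading lost regions were on chromosome 1 at 232404367 to 232405135 (fold enrichment 9.64 and 8.26) and chromosome 6 at 47119159 to 47119450 (10.5 and 11.5), and the leading gained region on chromosome 10 at 115095127 to 115095631 (13.1 and 14.5).

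Within strata of peak strength, FOXF1-bound p-c-JUN regions were absent from the knockdown libraries more often than other p-c-JUN regions, with odds ratios of 1.82 (95% interval 1.69 to 1.94) and 1.50 (1.34 to 1.66). Without strata the direction turned, to 0.777 and 0.673, since 15.5% of FOXF1-bound and 19.1% of other regions were absent from replicate 1, and 9.34% and 13.3% from replicate 2. Starting from 1 Sen list at a time, the odds ratios of absence from the other Sen library were 0.351 and 0.567, against 1.45 and 1.39 for knockdown library 1 and 1.13 and 1.14 for library 2. With lists of 70177 peaks, 5451 regions were gained and 5006 lost, against 1730 to 2176 for other pairs. The balance tipped both ways when 1 library was left out, with 8635 gained and 24150 lost without Sen replicate 1, and 17737 and 7558 without knockdown replicate 1. Leaving out a library lets 1 list decide presence for its condition and favours regions held by that condition, so these tips are partly built in. Peak number differed by less than the spread (log2 −0.01 ± 0.229, SE, n = 2 and 2; exact two-sided permutation p = 1, with 0.333 the smallest possible).

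**Figure D2:**
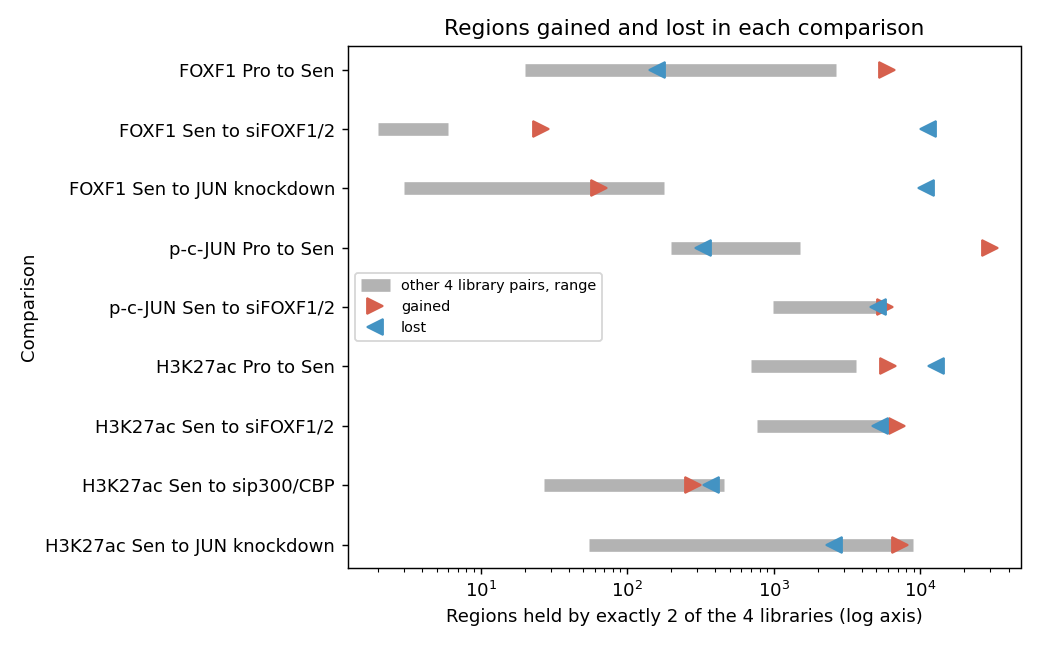
Regions gained (red) and lost (blue) in each of the 9 comparisons on a log axis, with the range of the 4 other library pairs in grey. FOXF1 after siFOXF1/2 (11215 lost) and p-c-JUN in senescence (29856 gained) lie far beyond the other pairs. For FOXF1, knockdown lists of 186 and 133 peaks cap what the other pairs can share. With lists of equal length, gained and lost were 56 and 67 for FOXF1 after siFOXF1/2, against 0 to 1 for other pairs. For p-c-JUN in senescence they were 4244 and 3510, against 558 to 583. Both classes after sip300/CBP (280 and 374) lie within 27 to 455, but with lists of equal length they were 221 and 107 against 45 to 60.

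In senescence, with the Sen libraries of the first deposit, more regions lost the H3K27ac mark than gained it, 12698 against 5988, both above the 697 to 3630 of other pairs. Gained regions were on chromosome 5 at 64227516 to 64228778 (fold enrichment 5.32 and 5.26) and chromosome 16 at 75539663 to 75540985 (7.74 and 6.72), and lost regions on chromosome 19 at 6076441 to 6077372 (8.88 and 7.68) and chromosome 5 at 10191824 to 10193280 (7.41 and 7.23). Regions that gained H3K27ac more often overlapped a p-c-JUN region gained in senescence than those that lost it, 30.9% (95% interval 29.1 to 32.8) against 6.82% (6.45 to 7.21), with 17.5% for regions held by all 4 libraries. The same held for gained FOXF1 regions, which 7.38% (6.61 to 8.01) of gained and 0.953% (0.816 to 1.11) of lost H3K27ac regions overlapped, though regions held by all 4 libraries did so more often, at 8.83%. Lost regions are absent from both Sen H3K27ac lists, which overlapped 85.6% and 68.3% of the FOXF1 regions of Sen cells. This FOXF1 contrast is thus partly set by construction.

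Peak number fell by 0.27 ± 0.243 on the log2 scale (SE, n = 2 and 2; exact two-sided permutation p = 0.667, with 0.333 the smallest possible). With lists of 60862 peaks, 6808 regions were gained and 8779 lost, against 1069 to 1919 for other pairs, and with all 4 Sen libraries required the gained regions numbered 657. The balance turned without Sen replicate 2, with 22045 gained and 14552 lost, though leaving out a Sen list in itself favours gained regions here. With the shorter Sen lists of the second deposit, a test added after the data had been seen, 1882 regions were gained and 31194 lost, and with those lists at equal length 4524 and 6703 (other pairs 637 to 838). Of the 1882 and 31194, 30.1% (95% interval 27.8 to 32.0) and 11.1% (10.7 to 11.4) overlapped a gained p-c-JUN region, while gained FOXF1 regions overlapped 4.04% (3.14 to 4.83) and 3.63% (3.41 to 3.85). At equal length the latter were 6.65% (5.68 to 7.83) and 4.77% (4.20 to 5.32).

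After siFOXF1/2, 6898 regions gained and 5343 lost H3K27ac, the first above and the second within the 770 to 6201 of other pairs. With lists of 60862 peaks both lay above, at 5776 and 5482 against 1467 to 2729. With all 4 Sen libraries required the lost regions numbered 308, and without Sen replicate 2 the balance turned, with 8520 gained and 22962 lost. Leaving out a Sen list in itself favours lost regions here. Lost regions overlapped FOXF1 regions of Sen cells more often than gained ones, 10.9% (95% interval 9.76 to 11.9) against 1.54% (1.25 to 1.80), and other pairs gave 2.60% to 5.66%, but regions held by all 4 libraries overlapped FOXF1 most often, at 19.5%. Gained regions are absent from both Sen H3K27ac lists, which overlapped 85.6% and 68.3% of the FOXF1 regions. The contrast between lost and gained regions is thus partly set by construction. Lost regions also overlapped p-c-JUN regions lost after siFOXF1/2, from separate libraries, at 7.47% (6.86 to 8.17). This compared with 0.623% (0.458 to 0.767) of gained ones and 2.74% of those held by all 4 libraries. Both lost classes require presence in Sen cells and absence after the knockdown, so this contrast too is partly set by construction. For all p-c-JUN regions of Sen cells the order was the reverse. They overlapped 24.0% of lost and 33.9% of gained H3K27ac regions (other pairs 21.8% to 35.6%). A region on chromosome 7 at 124282963 to 124283968 (fold enrichment 6.38 and 5.70 in Sen cells) was among the 10 named both as gained in senescence and as lost after siFOXF1/2, 2 comparisons that share the Sen libraries. The leading gained region was on chromosome 9 at 17090469 to 17091107 (8.06 and 7.83). Of the 10 named lost regions, 3 lay within 2 Mb of a longest peak-free stretch, but only 1.67% of all 5343 lost regions did.

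Within strata of strength, absence of FOXF1-bound H3K27ac regions from the knockdown libraries had odds ratios of 0.995 (95% interval 0.924 to 1.07) and 0.938 (0.874 to 1.00, the upper bound just under 1). Between the Sen libraries the odds ratios lay below 1: from the list of replicate 1 they were 0.583 for Sen replicate 2, against 0.862 and 0.821 for the knockdown libraries, and from that of replicate 2 they were 0.200, against 0.551 and 0.563. Alternatives went both ways, from 0.577 and 0.550 without strata to 1.30 and 1.07 at −log10 q of 5 or more. Peak number differed by less than the spread (log2 0.12 ± 0.268, SE, n = 2 and 2; exact two-sided permutation p = 1, with 0.333 the smallest possible).

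**Figure D3:**
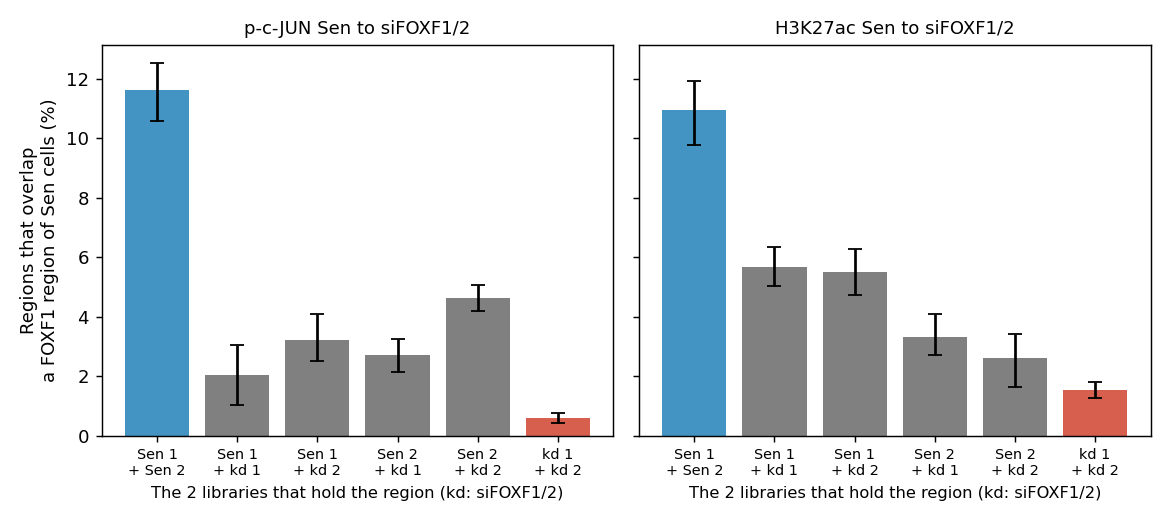
Percent of regions held by exactly 2 of the 4 libraries that overlap a FOXF1 region of Sen cells, for each pair of libraries, with 95% intervals over chromosomes; blue is lost, red gained and grey 1 library of each condition. For p-c-JUN the lost regions reach 11.6% and for H3K27ac 10.9%, against 0.593% and 1.54% of the gained regions. Gained regions are absent from both Sen lists, which overlap most FOXF1 regions of Sen cells, so this contrast is partly set by construction. Regions held by all 4 libraries, not drawn, overlapped FOXF1 more often than the lost ones.

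With p300 and CBP, the enzymes that deposit H3K27ac, knocked down, 374 regions were lost and 280 gained, and both lay within the 27 to 455 of other pairs. With lists of 1549 peaks, 107 were lost and 221 gained, both above the 45 to 60 of other pairs, and gained then outnumbered lost. They also did without knockdown replicate 1, at 1167 against 470, but without control replicate 2 the counts were 300 gained and 7341 lost. Each omission in itself favours regions held by the condition that lost a list. By FOXF1 overlap, the odds ratios of absence from the knockdown libraries were 0.859 (95% interval 0.516 to 1.65) and 0.519 (0.283 to 1.09). The knockdown libraries held 29.2% and 16.6% of the 565 regions shared by their own control libraries. The leading lost region was on chromosome 4 at 85907106 to 85908168 (fold enrichment 6.56 and 7.34), and the leading gained region on chromosome 2 at 92280846 to 92281517 (11.0 and 12.5). Of the 10 named gained regions, 8 lay within 2 Mb of the longest peak-free stretch of their chromosome, and none of the 10 lost. Over all regions the shares were 16.1% of the 280 gained and 1.87% of the 374 lost. Peak number fell by 0.69 ± 1.23 on the log2 scale (SE, n = 2 and 2; exact two-sided permutation p = 0.667, with 0.333 the smallest possible). At −log10 q of 5 or more the direction turned, to 0.64, and the control libraries shared only 6.83% and 27.6% of their peaks.

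JUN knockdown cells, set against the Sen libraries of the same deposit, gained H3K27ac at 7255 regions and lost it at 2595. Both counts lay within the 55 to 8964 of other pairs, where the knockdown lists held 74484 and 29606 peaks. With lists of 26694 peaks they were 4080 and 3848, above the 601 to 1450 of other pairs. Without Sen replicate 4 the balance turned, with 7989 gained and 15054 lost, though leaving out a Sen list in itself favours lost regions. Lost regions overlapped p-c-JUN regions of Sen cells more often than gained ones, 50.8% (95% interval 48.6 to 52.9) against 30.2% (28.9 to 31.3), but other pairs gave 28.8% to 55.5% and regions held by all 4 libraries 62.0%. FOXF1 regions overlapped 6.59% (5.50 to 7.56) of lost and 8.31% (7.56 to 8.88) of gained regions, against 9.09% to 12.7% for other pairs and 22.6% for regions held by all 4. Leading lost regions were on chromosome 8 at 48565218 to 48566121 (fold enrichment 7.51 and 6.10) and chromosome 1 at 59480792 to 59482006 (5.58 and 5.82). The leading gained region was on chromosome 11 at 85195022 to 85195297 (24.2 and 29.0). It was 276 bp wide, against a median of 638 bp for gained regions, and the median fold of the 2 knockdown lists was 4.41 and 4.32. No filter for artifact-prone regions was applied here, so it may not be a gain of the mark.

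The odds ratios of absence by p-c-JUN overlap went in opposite directions in the 2 knockdown libraries, 0.798 (95% interval 0.720 to 0.886) and 1.22 (1.15 to 1.28). By FOXF1 overlap they were 0.371 (0.319 to 0.427) and 0.682 (0.611 to 0.762), with FOXF1-bound regions absent less often. The same direction held between unperturbed libraries: starting from 1 Sen list, the odds ratios of absence from the other Sen library were 0.781 and 0.527 by FOXF1 overlap, against 0.310 and 0.318 for knockdown library 1 and 0.554 and 0.575 for library 2. By p-c-JUN overlap they were 0.616 and 0.771, against 0.494 and 0.624 for knockdown library 1 and 0.809 and 0.991 for library 2. Those of library 2 thus no longer lay above 1 in strata of strength. In strata of strength and width, single Sen lists gave 0.539 and 0.671 for library 1 and 0.906 and 1.08 for library 2. With regions of both Sen lists, library 2 gave 1.32 in those strata and 1.45 at −log10 q of 5 or more. Library 1 gave 0.860 and 1.07. Peak number differed by less than the spread (log2 0.38 ± 0.796, SE, n = 2 and 2; exact two-sided permutation p = 0.667, with 0.333 the smallest possible), and turned to −0.12 with all 4 Sen libraries.

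The last comparison was of co-occupancy. In senescent cells the p-c-JUN lists overlapped 76.3% and 84.7% of the 11287 FOXF1 regions, against 2.38% and 3.05% for shifted regions (mean 80.5% ± 5.98, SD, n = 2). H3K27ac overlapped 85.6% and 68.3% (76.9% ± 12.3, SD, n = 2) in the first deposit, against 3.42% and 2.22%, but only 52.0% and 30.5% in the shorter Sen lists of the second deposit, against 1.74% and 0.909%. In Pro cells the shorter p-c-JUN lists overlapped 45.4% and 53.2% of the same regions, against 0.828% and 1.05% for shifted regions. H3K27ac already overlapped 78.0% and 78.8%. These FOXF1 regions were chosen in Sen cells. Of the 2695 FOXF1 regions held by both Pro libraries, the Pro p-c-JUN lists overlapped 72.2% and 78.4%, and the Sen lists 83.8% and 86.9%. After siFOXF1/2, p-c-JUN overlapped 65.3% and 72.6%, below both Sen libraries, and H3K27ac 74.5% and 67.8%. With FOXF1 and p-c-JUN summits required within 200 bp the mean was 61.8%, and with H3K27ac at −log10 q of 5 or more 56.1%.

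**Figure D4:**
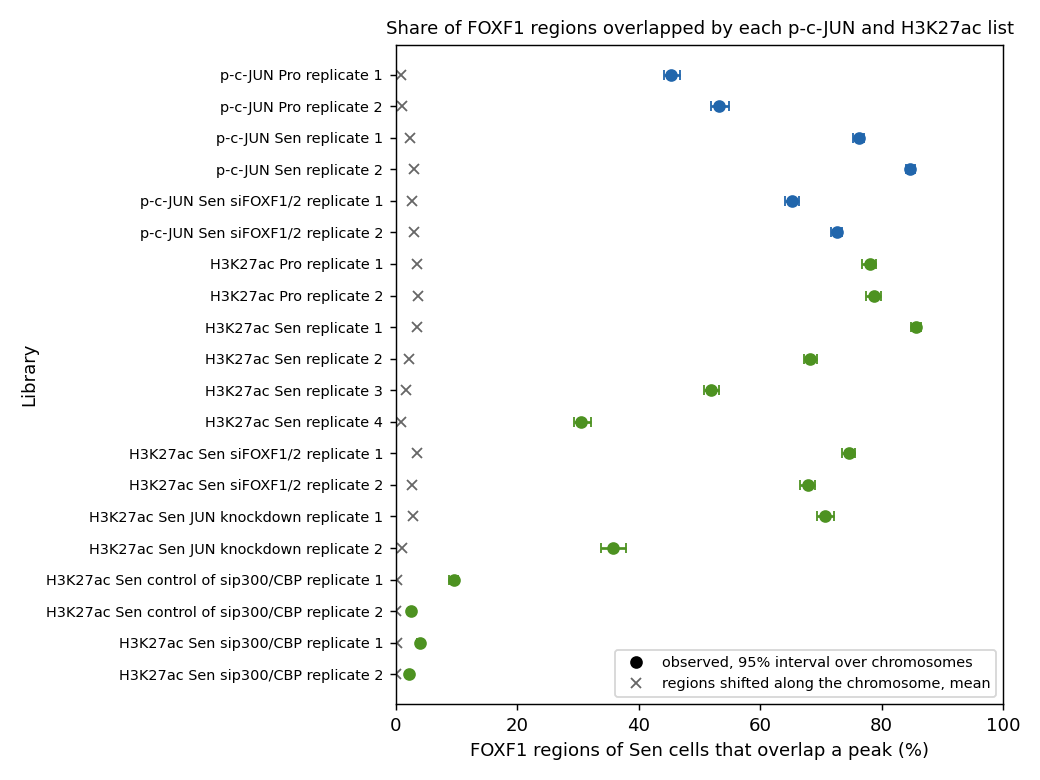
Percent of the 11287 FOXF1 regions of Sen cells that overlap a peak of each p-c-JUN (blue) and H3K27ac (green) library, with 95% intervals over chromosomes, and crosses for regions shifted along the chromosome. The p-c-JUN libraries rank from 45.4% and 53.2% in Pro cells to 76.3% and 84.7% in Sen cells, with siFOXF1/2 between them. The regions were chosen in Sen cells, and the Pro p-c-JUN lists are shorter, which both lower the Pro values.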

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

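Alternatives were set before the data were examined, except the strata of strength and width, the omission of replicates from overlap shares and from odds ratios, and the use of the second-deposit Sen libraries for H3K27ac in senescence, which were chosen after seeing the data. Of 57 alternative log2 ratios of peak number, 46 kept their direction and 11 reversed. The 46 include 8 from the replicate block, which could not change direction. Of 134 region counts, 65 stayed within 1.5 times, and an overlap of 50% kept all 18. The cause of each change was not tested unless stated.

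At −log10 q of 5 or more, log2 ratios reversed for p-c-JUN after siFOXF1/2 (0.0285) and H3K27ac after sip300/CBP (0.64), and the other 7 kept direction. Gained regions were 2884 for FOXF1 in senescence, 2236 for H3K27ac in senescence, 3748 for H3K27ac after siFOXF1/2, 43 after sip300/CBP and 1880 after JUN knockdown. Lost regions were 5302 and 5270 for FOXF1 after siFOXF1/2 and JUN knockdown, and for H3K27ac 2141 after siFOXF1/2, 6 after sip300/CBP and 882 after JUN knockdown.

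With lists of equal length, gained and lost were 864 and 635 (FOXF1 in senescence), 56 and 67 (FOXF1, siFOXF1/2), 131 and 206 (FOXF1, JUN knockdown) and 4244 and 3510 (p-c-JUN in senescence). H3K27ac lost 107 after sip300/CBP and gained 4080 after JUN knockdown. With all 4 Sen libraries, H3K27ac gained 657 in senescence, lost 308 after siFOXF1/2, and gained 3300 and lost 1349 after JUN knockdown, whose log2 ratio reversed to −0.12. With the second-deposit Sen libraries, H3K27ac in senescence gained 1882 and lost 31194 (log2 ratio −1.26), and overlapped 41.3% of FOXF1 regions.

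Leaving out each replicate moved most region counts, since 1 library then decides presence for its condition, which favours regions held by that condition. Gained and lost ranged from 6138 to 31811 and from 194 to 2470 for FOXF1 in senescence, 31 to 66 and 11222 to 40449 after siFOXF1/2, and 78 to 415 and 11057 to 39999 after JUN knockdown. For p-c-JUN they ranged from 32630 to 61299 and 646 to 2327 in senescence, and 8635 to 17737 and 7558 to 24150 after siFOXF1/2. For H3K27ac they ranged from 8160 to 22045 and 14552 to 28821 in senescence, 8520 to 24052 and 7412 to 22962 after siFOXF1/2, 300 to 3330 and 400 to 7341 after sip300/CBP, and 7989 to 39682 and 2687 to 15054 after JUN knockdown. Log2 ratios that reversed spanned −0.22 to 0.20 (p-c-JUN, siFOXF1/2), −0.12 to 0.36 (H3K27ac, siFOXF1/2), −1.69 to 0.32 (sip300/CBP) and −0.29 to 1.04 (H3K27ac, JUN knockdown). FOXF1 overlap ranged from 64.6% to 84.7% for p-c-JUN and 62.0% to 85.6% for H3K27ac, with 61.8% for summits within 200 bp and 56.1% for H3K27ac at the stricter threshold.

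Odds ratios of loss at FOXF1 sites for p-c-JUN reversed to 0.777 and 0.673 without strata. For H3K27ac after siFOXF1/2 they were 0.577 in library 1 without strata, 1.30 and 1.07 at the stricter threshold, 1.25 and 1.17 with width strata, and 0.551 to 0.862 in library 1 with replicates left out. For H3K27ac after JUN knockdown by p-c-JUN overlap they were 1.07 in library 1 at the stricter threshold. In library 2 they were 1.01 without strata, 0.809 to 0.991 with replicates left out, 1.45 at the stricter threshold and 1.32 with width strata. By FOXF1 overlap library 2 gave 0.830 at the stricter threshold, with the interval reaching 1. After sip300/CBP they were 0.490 and 0.261 without strata, 0.419 with width strata in library 2, 0.610 to 0.879 in library 1 and 0.307 to 0.568 in library 2 with replicates left out.

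Replicate numbers were shared without a stated pairing. A replicate block cannot change a log2 ratio with 2 pairs, only its SE, which ran from 0.229 to 1.23 without it and from 0.0199 to 1.03 with it (FOXF1 in senescence 1.15 and 0.0546, FOXF1 after siFOXF1/2 0.824 and 1.03). For odds ratios the block set each knockdown library against the Sen or control list of its own number alone. This changed the regions tested and gave the same values as leaving the other replicate out. The odds ratios were 1.45 and 1.14 for p-c-JUN, 0.862 and 0.563 for H3K27ac after siFOXF1/2, and 0.879 and 0.307 after sip300/CBP. Their shift from the main test thus does not isolate a pairing of replicates. The intervals of 0.862 and 0.307 excluded 1, unlike those of the same libraries in the main test. Those of 1.45, 1.14 and 0.563 (0.527 to 0.597) excluded 1, as in the main test. Replicate 2 had the longer list in 7 of 13 groups, but the difference (log2, replicate 2 minus 1) went by antibody. For p-c-JUN it was 0.373, 0.413 and 0.199 in Pro, Sen and siFOXF1/2 cells. For FOXF1 it was 1.68 and 1.58 in Pro and Sen cells, 1.22 after JUN knockdown and −0.484 after siFOXF1/2. For H3K27ac it was negative in every group except Pro (0.0835). A batch shared by libraries of the same replicate number therefore stays open. Gene list windows and motif scans were not run, and the loss test at the stricter threshold after sip300/CBP had too few regions.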

Other observations

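The overlap, peak-free stretch, threshold, enrichment, processing run and deposit tests in this part, the pileup test for JUN knockdown and the odds starting from 1 Sen list were chosen only after the result was seen. Regions that lost H3K27ac after JUN knockdown were measured against second-deposit Sen libraries, and so share no library with the senescence comparison of the first deposit. Of these lost regions, 13.8% (95% interval 12.6 to 15.1) overlapped a region that gained H3K27ac in senescence, against 0.956% of regions held by all 4 libraries and 0% to 4.24% of those held by 1 Sen and 1 knockdown library. Lost regions must be present in Sen cells, as regions gained in senescence are, so regions present in Sen cells were also compared with each other. Starting from 1 Sen list at a time, within strata of strength, regions that overlapped one gained in senescence had odds ratios of absence from the knockdown libraries of 3.12 to 6.84, against 1.10 (0.970 to 1.29) and 1.36 (1.14 to 1.61) for absence from the other Sen library. Regions that gained p-c-JUN in senescence overlapped 29.2% (27.2 to 30.9) of the lost regions, against 13.4% of those in all 4 libraries and 14.4% to 18.4% of those held by 1 Sen and 1 knockdown library.

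The few FOXF1 peaks called after knockdown lay near peak-free stretches of the genome more often than those of the long lists. Within 2 Mb of each chromosome's longest stretch free of peaks in all lists, such as the 21.1 Mb stretch of chromosome 1 around its centromere, lay 62.9% and 60.2% of the peaks after siFOXF1/2 and 41.0% and 17.1% after JUN knockdown. In the 19 lists of more than 10000 peaks the share was 1.26% to 2.03%. Among the other short lists it was 4.40% and 8.33% for H3K27ac after sip300/CBP, 1.93% and 3.62% in its control, and 3.78% for FOXF1 in Pro replicate 1. Most peaks after siFOXF1/2 also overlapped FOXF1 peaks of Sen cells, from 57.5% to 68.4% by library pair, as did 28.5% to 55.0% of the peaks after JUN knockdown. Lists of other antibodies overlapped the siFOXF1/2 peaks too, 60.8% to 75.2% for p-c-JUN and 22.6% to 55.6% for H3K27ac in Sen cells, 31.7% to 40.6% for the sip300/CBP control, and 62.4% and 66.9% after sip300/CBP.

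The loss of FOXF1 peaks after siFOXF1/2 might come from shallower or shorter-fragment libraries. When summit pileups of the Sen peaks were scaled to each knockdown library, 8.68% to 31.5% (987 to 3566 peaks) would still have been called. The knockdown lists held 186 and 133 peaks in all. This argues against depth as the whole cause, as far as the background of so few peaks measures depth. At most 4.66% of the peaks still called held a knockdown peak, but such short lists cap that share, so it cannot decide. The lowest −log10 q lay 0.916 higher in 1 knockdown list, but at −log10 q of 5 or more in every list the log2 ratio was still −6.32 ± 0.883 (SE), which argues against a stricter q threshold as the whole cause. Weak enrichment stays open: the 2 first-deposit H3K27ac control groups of Sen cells differed by −4.13 on the log2 scale (17.5-fold), less than the 7.22 by which FOXF1 peak number fell. Another processing run stays open as well, as these lists had another name prefix and a narrowest peak of 76 bp, and no list of unperturbed cells shared them, so loss of the FOXF1 protein, the biological explanation in the design, could not be separated from either.

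For the FOXF1 lists after JUN knockdown, estimated depth was higher than in Sen cells (3.50 and 3.09 against 2.44 and 2.70 fragments per kb). At least 99.2% of scaled Sen peaks (11220) would still have been called, while the knockdown lists held 378 and 883 peaks. This argues against depth as the cause only as far as the estimate holds, since the lowest background among so few peaks may overstate depth. At most 2.01% of the peaks still called held a knockdown peak, a share that such short lists cap. The deposit may contribute: H3K27ac peak number in Sen cells was −0.99 on the log2 scale in the second deposit relative to the first, well short of the −5.35 of FOXF1, but no FOXF1 library of unperturbed cells stood in the second deposit. Weak enrichment also stays open, given the −4.13 between control groups. An effect of JUN knockdown on FOXF1 binding is a hypothesis that these libraries do not separate from the deposit.

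At equal peak strength, p-c-JUN regions at FOXF1 sites may be more sensitive to siFOXF1/2 than others. Chance loss between libraries would give similar odds within Sen cells, yet these were at most 0.708 in strata of strength and width, and below 1 both ways, against 1.37 to 1.79 for the knockdown libraries. The choice of FOXF1 regions in the same Sen state is argued against, though not excluded, by odds ratios of absence from the Pro libraries of 0.526 to 0.604, since Pro cells also differ in state. Of lost p-c-JUN regions 1.72% overlapped FOXF1 regions of Pro cells against 0.227% of gained ones. Regions held by 1 Sen and 1 knockdown library gave 0.362% to 1.52%. Gained regions are absent from both Sen p-c-JUN lists, which overlapped 83.8% and 86.9% of the Pro FOXF1 regions, so their share is low partly by construction. Most Pro regions were also Sen regions, so the choice of FOXF1 regions stays open. Without strata the direction was the opposite, at 0.777 and 0.673, so the pattern rests on comparing peaks of like strength.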
